A study of Mus musculus with 12 samples.

How the data were processed

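RNA was measured by sequencing in 12 libraries of CMM cells, a transplantable GFP-marked mouse model of acute myeloid leukaemia with inv(16). Per the labels' protocols, the cells were engrafted into C57BL/6 mice, and treatment began when about 1% of blood cells carried GFP. The mice received 3 intravenous injections, given on alternate days, of PBS, CpG-scrODN or CpG-STAT3dODN. Spleens were taken 1 day after the last injection, and c-Kit positive cells were enriched from a single cell suspension with a positive selection kit before total RNA was extracted. Libraries were made with an Illumina RNA-seq preparation kit, per the labels' protocols. The series design text adds that GFP positive cells were sorted, a step that the extraction protocol does not list. CpG oligonucleotides are ligands of the endosomal receptor TLR9. The STAT3 decoy part carries a DNA sequence that STAT3 binds, and the scrambled part is its control.

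The deposited unit was RPKM, reads per kilobase of transcript scaled to the mapped reads of the library, per the file headers and labels, with 24310 named features in each library. The submitters' processing notes name the genome build mm10, TopHat 1.3.1 and Partek 6.12.0713, without saying which step each tool performed. The filters and the gene annotation behind the values are not given in the sources used here, and reads were not analysed here. Values were used as the authors deposited them. Features were matched by gene symbol, and coordinates of named genes came from the RefSeq annotation of the GRCm38 assembly, which mm10 denotes. In 27 features the symbol had been turned into a date, and none of these is named.

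The group of every library was taken from its sample label, with 4 libraries per group. In all 12 files the group word in the column header and in the file's own name differed from the label. The libraries labelled PBS were headed DEC, those labelled CpG-scrODN were headed PBS, and those labelled CpG-STAT3dODN were headed SCR. DEC and SCR are read here as the decoy and the scrambled oligonucleotide. Both names are therefore given for each group, every comparison is one between labelled groups, and no direction is assigned to a treatment. Nothing in the labels says that 1 library stands for 1 mouse, so p-values measure only the spread between these samples, which may be technical.

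Depth was estimated from genes with a single transcript in the GENCODE annotation, 139 to 203 of them per library, using the RPKM that 1 read is worth. It lay between 31610000 and 36360000 reads, a ratio of 1.15. At the lowest depth, an RPKM of 1 stands for about 31.6 reads per kilobase. Of the low values of single-transcript genes, 59.9% to 62.9% came out as whole reads within 0.05 of a read. This was too few to recover reads for all genes, so no count test was run. No pair of libraries held identical values. Within groups, the chi-square per degree of freedom of estimated reads was 15.65 to 343.96 per pair, far above sampling noise, and each library was counted separately.

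Values were analysed as log2(RPKM + 1), a scale that understates the change of low genes. Genes with an RPKM of at least 1 in at least 4 of the 12 libraries were kept, which left 10886. One limma 3.58.1 model in R 4.3.3 held the 3 labelled groups over all 12 libraries, with moderated variances and an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. Intervals are 95% intervals from the same model and are not adjusted for the number of genes.

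Of 36 gene lists written down before the data were examined, 33 had at least 5 measured members and were tested. They cover the genes named with the study, interferon and TLR9 responses, STAT3 targets, antigen presentation, myeloid and stem cell programs, growth, metabolism and stress, RNA quality, and markers of other spleen cells. The NK cell and stroma lists had 4 measured members each and the mitochondrially encoded list had 0, so these were not tested. Lists were tested with camera at its preset correlation of 0.01, then with an estimated correlation, and with fry, each adjusted over the 33 lists. For list means per library, an exact permutation test of 4 against 4 libraries was used, two-sided, whose smallest p is 0.0286. The genes named were the 8 largest rises and the 8 largest falls among called genes with a mean RPKM of at least 1, groups that did not overlap and a symbol that is not a predicted model, clone or small RNA. To these were added up to 4 called members with the largest change in each called list, and all genes named with the study. Of the genes these rules gave, 2 are not reported here; they were tested with all others and stay in every count of calls and list result.

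The model and camera were tested on simulated data, drawn for the 10886 genes from their overall means and moderated variances, with 50 genes changed at each size. For CpG-scrODN against PBS, 38% of genes changed by 0.5 on the log2 scale were recovered, 84% of those changed by 1, 100% of those changed by 2 and 98% of those changed by 3, with 6 false calls among 166. For CpG-STAT3dODN against PBS the shares were 36%, 86%, 96% and 100%, with 8 false calls among 167. For CpG-STAT3dODN against CpG-scrODN they were 34%, 92%, 100% and 100%, with 11 false calls among 174. A B-cell list shifted by 1 was called in each of the 3 simulations, and 0 of the other 32 lists were called by camera at the preset correlation. Genes were drawn independently of each other. The simulations therefore cannot show how often camera makes false calls on lists whose genes are correlated. Libraries were drawn independently as well, without any structure shared between them. The counts of false gene calls therefore do not cover such structure.

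The alternatives tried were the file names' grouping, pseudocounts of 0.1 and 0.5, no filter, an RPKM floor of 5, quantile normalization, size factor scaling, limma without the trend, library quality weights, and a fit on 2 groups only. A replicate block, a fold change of at least 1.5, and each library of a comparison left out in turn were also tried. The library quality weights were the same in all 3 comparisons, and their estimate did not fully converge. After the data were seen, 4 more were added. They left out the replicate 4 libraries labelled PBS and CpG-STAT3dODN, or all 3 libraries numbered 4, or added a term for replicate 4, or added the mean of the B-cell list as a covariate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.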

Results

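Gene expression was measured in c-Kit enriched spleen cells from mice carrying CMM leukaemia, in 4 libraries labelled PBS, 4 labelled CpG-scrODN and 4 labelled CpG-STAT3dODN. The study asked how combined TLR9 stimulation and STAT3 inhibition acts on the differentiation of these leukaemia cells. The column headers gave every library another group than its label, so each group is named by label and header together: labelled PBS (headed DEC), labelled CpG-scrODN (headed PBS) and labelled CpG-STAT3dODN (headed SCR). Estimated depth was 31610000 to 36360000 reads per library. Correlations of log2 values within groups ran from 0.9291 to 0.9883 for the libraries labelled PBS, from 0.9839 to 0.9968 for those labelled CpG-scrODN, and from 0.9282 to 0.993 for those labelled CpG-STAT3dODN.

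Replicate 4 of the libraries labelled PBS and replicate 4 of those labelled CpG-STAT3dODN stood apart from the rest. Fos, an immediate-early transcription factor singled out after its values were seen, was at 12.9 and 5.91 RPKM in these libraries against 486 to 1160 in the other 10. The mean of the immediate-early and heat-shock list in these 2 libraries was 4.21 on the log2 scale, and the lowest of the other 10 was 5.83. Of its 21 measured members, 11 were lower in both libraries than in each of the other 10. The B-cell marker list set the libraries labelled PBS apart, with means of 3.53 to 4.66 in the libraries labelled PBS, 0.97 to 1.59 in those labelled CpG-scrODN and 1.53 to 2.42 in those labelled CpG-STAT3dODN. Both facts bear on each comparison that follows.

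**Figure D1:**
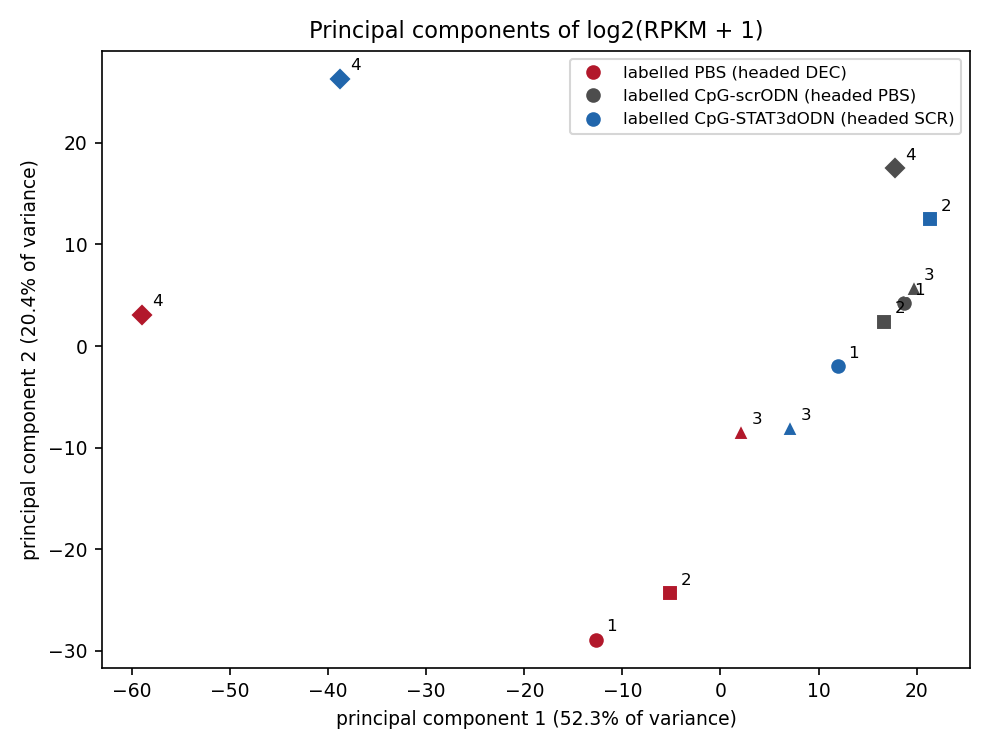
Principal components 1 (52.3% of variance) and 2 (20.4%) of log2(RPKM + 1) over 10886 genes; each point is a library, coloured by labelled group and marked with its replicate number. Replicate 4 labelled PBS and replicate 4 labelled CpG-STAT3dODN lie at -59 and -38.8 on component 1, and the other 10 libraries lie between -12.7 and 21.4.

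The first comparison set the libraries labelled CpG-scrODN (headed PBS) against those labelled PBS (headed DEC). By the labels it asks what the control oligonucleotide changed, and by the headers it sets untreated cells against decoy-treated cells. Irf8, a transcription factor of monocyte, dendritic and B-cell development at chromosome 8, 120736358 to 120756694 (mm10, as all positions here), was at 25.3 ± 11.7 RPKM (SD, n = 4) in the libraries labelled PBS and at 3.34 ± 0.861 in those labelled CpG-scrODN. The difference was 2.53 ± 0.27 on the log2 scale (SE, limma adjusted p = 0.000265). Mpo, the myeloperoxidase of primary granules at chromosome 11, 87793784 to 87804412, was at 100 ± 12.6 against 23.6 ± 7.32 RPKM (SD, n = 4 each), higher by 2.08 ± 0.29 (SE, limma adjusted p = 0.00139). Cd79a, a chain of the B-cell receptor complex at chromosome 7, 24897497 to 24901858, was at 86.5 ± 67.8 against 4.94 ± 2.23 RPKM, higher by 3.70 ± 0.50 (SE, limma adjusted p = 0.0012). Stat3 itself, at chromosome 11, 100886806 to 100939594, was at 43.2 ± 6.82 and 45 ± 1.56 RPKM, a difference of 0.07 with a 95% interval of -0.21 to 0.35, and did not pass.

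In all, limma called 452 of 10886 genes, 12 higher in the libraries labelled CpG-scrODN and 440 higher in those labelled PBS. With quantile normalization these numbers were 75 and 318. At an unadjusted p under 0.05 there were 1702. The 2 groups did not overlap in 13.9% of genes, where chance gives 2.86%. Camera called 23 of 33 lists, 5 higher and 18 lower in the libraries labelled CpG-scrODN. Of these calls 2 held with an estimated correlation and 15 with fry. All 16 measured genes of the B-cell list passed over all genes, higher in the libraries labelled PBS, and 16 passed adjusted over the list alone, with a list median of 2.64. Its mean per library differed by 2.71 (exact permutation p = 0.0286, 0.0629 after adjustment over the lists). Cd79b and Ms4a1, which encodes CD20, were higher by 3.97 and 3.84. Camera called the list (adjusted p = 2.53e-31), and it also passed with an estimated correlation (adjusted p = 0.0333). Of the plasma cell list 4 of 7 genes passed (5 adjusted over the list alone), Mzb1 and Jchain by 3.09 and 2.92, and of the T-cell list 3 of 6 passed (5 adjusted over the list alone, 1 of them in the other direction), Cd2 by 3.14. Their calls were lost, with adjusted p = 0.0924 and 0.121 with an estimated correlation. In replicates 1 to 4 labelled PBS, Cd2 was at 13.1, 6.84, 9.36 and 38.6 RPKM. Cd79a was there at 66.4, 45, 47.6 and 187 RPKM, in the same order. In the libraries labelled CpG-scrODN, where both were low, the order differed. Cd3g and Lck, which also passed, did not follow the Cd79a order in the libraries labelled PBS. In replicates 1 to 4 there, Cd3g was at 1.86, 2.42, 1.87 and 4.05 RPKM. Lck was at 2.69, 2.39, 1.85 and 4.75 RPKM. Each was highest in replicate 4, as Cd79a was. No library separates cell types, so these orders do not decide whether the T-cell list holds a signal apart from the B-cell list.

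Of 16 measured genes of MHC class II presentation and costimulation, 12 passed over all genes and 14 adjusted over the list alone, higher in the libraries labelled PBS, where the B-cell list was also higher. The list median was 1.87, and adjusted p = 0.0926 with an estimated correlation. H2-Eb1, a class II beta chain, was at 150 ± 112 against 18.7 ± 4.91 RPKM, Cd74, the class II invariant chain, was higher by 2.69, H2-DMb2 by 3.05, and Ciita, the class II transactivator, by 2.13 ± 0.29 (SE, limma adjusted p = 0.00134). In the MHC class I list 4 of 22 passed (5 adjusted over the list alone), among them H2-Q7 and Nlrc5, the class I transactivator, by 2.29 and 1.65, with adjusted p = 0.302 with an estimated correlation. The H2-Q genes are close relatives and may share reads.

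Of 20 primary granule genes, 12 passed over all genes and 15 adjusted over the list alone, higher in the libraries labelled PBS with a median of 0.85. Prtn3 and Ctsg, granule proteases, were higher by 2.05 and 2.09 (adjusted p = 0.121 for the list with an estimated correlation). Of 28 monocyte and macrophage genes, 9 passed over all genes and 15 adjusted over the list alone, among them Ms4a4c by 2.40 and Ly6c2 by 1.67, with adjusted p = 0.121 with an estimated correlation. In the granulocyte maturation list only Cebpe passed of 23 (8 adjusted over the list alone), higher by 1.36, with adjusted p = 0.455 with an estimated correlation. In the conventional dendritic list Cd83 and Wdfy4 passed of 7 (6 adjusted over the list alone), with adjusted p = 0.0333 with an estimated correlation. Without the filter on low values, which adds members, its median went from -1.82 to -0.101 and the call was lost (adjusted p = 0.491). In the plasmacytoid dendritic list 5 of 9 passed (6 adjusted over the list alone, 1 of them in the other direction), Ly6d by 4.37 and Spib by 3.17, with adjusted p = 0.0866 with an estimated correlation. With an RPKM floor of 5 its median turned from -0.66 to 0.112 and the call was lost (adjusted p = 0.129). Ly6d and Spib are also expressed by B cells. No library separates cell types, so neither dendritic list shows a signal apart from the B-cell list.

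Innate response genes were called on few members. The type I interferon list, with a median of 0.39 higher in the libraries labelled PBS, had 4 of 34 passing, Ifi27l2a, Ifi203, Trim30a and Cmpk2 by 2.20, 1.66, 1.48 and 1.07, and 12 adjusted over the list alone. Camera called it (adjusted p = 2.18e-06), with adjusted p = 0.278 with an estimated correlation. The interferon gamma list had 4 of 22 passing (12 adjusted over the list alone), Ciita, Nlrc5, Gbp9 and Gbp4, with close Gbp relatives that may share reads, and adjusted p = 0.302 with an estimated correlation. The list of TLR9 and NF-kB response genes had 7 of 27 passing (12 adjusted over the list alone, 1 of them in the other direction), among them the chemokines Ccl5 and Ccl3 by 1.69 and 1.31 and Cd40 by 1.61, with adjusted p = 0.302 with an estimated correlation. Tlr9 and its trafficking partner Unc93b1 were the 2 of 24 TLR9 signalling genes that passed (4 adjusted over the list alone), by 1.67 and 2.25, with adjusted p = 0.302 for the list with an estimated correlation.

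A smaller set was higher in the libraries labelled CpG-scrODN. Egr4, an immediate-early transcription factor, was at 4.48 ± 2.62 against 0.475 ± 0.352 RPKM (SD, n = 4), and Perp, Abcg1, a cholesterol exporter, Bex4, Ephx4, Asap2, Cdkn1a, the cell cycle inhibitor p21, and Rarres1 differed by 0.97, 0.82, 0.57, 0.51, 0.43, 0.41 and 0.39. Camera called the stem and progenitor, glycolysis, immediate-early, ribosomal protein and megakaryocyte lists as higher there, with medians of 0.08, 0.12, 0.44, 0.05 and 0.43. All 5 calls were lost with an estimated correlation, with adjusted p = 0.182, 0.455, 0.519, 0.532 and 0.155. The sign of the immediate-early median came from replicate 4 labelled PBS, at a list mean of 4.35 against 6.23 to 7.07 in replicates 1 to 3. Without it the median was -0.073 and the call was lost (adjusted p = 0.364). In these 5 lists 0 genes passed limma over all genes or adjusted over the list alone, and fry called the megakaryocyte list alone. The cell cycle, unfolded protein response and mature neutrophil lists were called as lower, with medians of -0.22, -0.21 and -0.68 and 0, 1 and 0 genes passing, the 1 being Dnajb9. With an estimated correlation their adjusted p was 0.592, 0.452 and 0.601. The genes named with the study were called as a list (4 of 16 passed, 6 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation). These 4 were Irf8, Ciita, Tlr9 and Itgam, and the list was chosen with the study's title in view. Kit, Spi1, Cebpa, Runx1, Cbfb, Myc and Socs3 did not pass over all genes. Their differences, labelled CpG-scrODN minus labelled PBS, were 0.747, -0.195, -0.715, 0.196, -0.049, -0.319 and -0.76. Lists that camera did not call were STAT3 targets (median -0.28), DNA and histone modifiers (-0.05), MYC and ribosome biogenesis (-0.02), p53 targets (-0.01), checkpoint ligands (0.02), oxidative phosphorylation (0.01), cholesterol synthesis (-0.32), erythroid (-0.38), red pulp macrophage (-0.29, mean 0.01) and mast cell (0.30). Of these, 3 STAT3 targets, 2 mast cell genes and 1 red pulp gene passed as lower, and of p53 targets 2 passed as higher and 3 as lower. Fry, unlike camera, called the STAT3 target and p53 target lists (fry adjusted p = 0.00285 and 0.0203). For erythroid, p53, modifier and MYC lists camera's direction, taken against all other genes, was opposite to the sign of the median.

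With the B-cell list mean as a covariate limma called 0 genes in this comparison (lowest adjusted p = 0.143), and the group explained 0.92 of the variance of that mean. Limma called 279 genes without replicate 3 labelled CpG-scrODN, 686 without both libraries of low Fos, 163 with an RPKM floor of 5, 871 with a term for replicate 4 and 1812 with library quality weights (730 higher and 1082 lower). The 12 genes higher in the libraries labelled CpG-scrODN became 4, 3 and 1 without its replicates 1, 2 and 3, 4 and 104 without replicates 1 and 3 labelled PBS, 111 and 114 without both libraries of low Fos or all 3 numbered 4, 176 with the replicate 4 term, 52 with the replicate block, 26 with size factor scaling, 19 without the filter, 18 with 2 groups only and 3 with the floor. On leaving out 1 library, camera lost the calls of the immediate-early list (without replicate 4 labelled PBS or CpG-scrODN), the glycolysis list (without replicate 3 or 4 labelled PBS or replicate 4 labelled CpG-scrODN, with medians of 0.075, 0.032 and 0.03), the TLR9 signalling list (without replicate 3 or 4 labelled PBS, with medians of -0.24 and -0.095), the unfolded protein response list (without replicate 1, 2 or 4 labelled PBS or replicate 4 labelled CpG-scrODN) and the mature neutrophil list (without replicate 2 or 3 labelled PBS or replicate 3 or 4 labelled CpG-scrODN, with medians of -0.481, -0.307, -0.446 and -0.547). Limma's calls of Egr4, Perp, Bex4, Ephx4, Asap2, Cdkn1a, Rarres1, Cebpe, Cd83, Cmpk2, Gbp4, Ccl3, Itgam, Lag3 and Tcf4 were each lost without at least 1 of the libraries, with differences within 1.5 times of the value from all libraries, and that of Dnajb9 was lost with quantile normalization. Camera's calls also ended without the filter for the stem and progenitor and megakaryocyte lists (medians of 0.019 and 0.098), with the floor for the NF-kB response, study gene and mature neutrophil lists (-0.301, -0.122 and -0.814), with quantile normalization for the stem and progenitor, glycolysis, immediate-early and ribosomal protein lists, with size factor scaling for the immediate-early list, and with quality weights for the glycolysis and immediate-early lists (-0.041 and -0.043). They ended without all 3 libraries numbered 4 for the stem and progenitor, glycolysis and immediate-early lists (0.069, -0.027 and -0.06), and for the last 2 without both libraries of low Fos as well. With a pseudocount of 0.1 the differences of Egr4, whose call was then lost, Perp, Cmpk2, Nlrc5, Gbp9, Gbp4, Cd40, Tlr9, H2-Q6, Derl3, Cd3g, Lck and Tcf4 were over 1.5 times as large, and that of Gbp4 fell to -0.911 without all 3 libraries numbered 4.

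**Figure D2:**
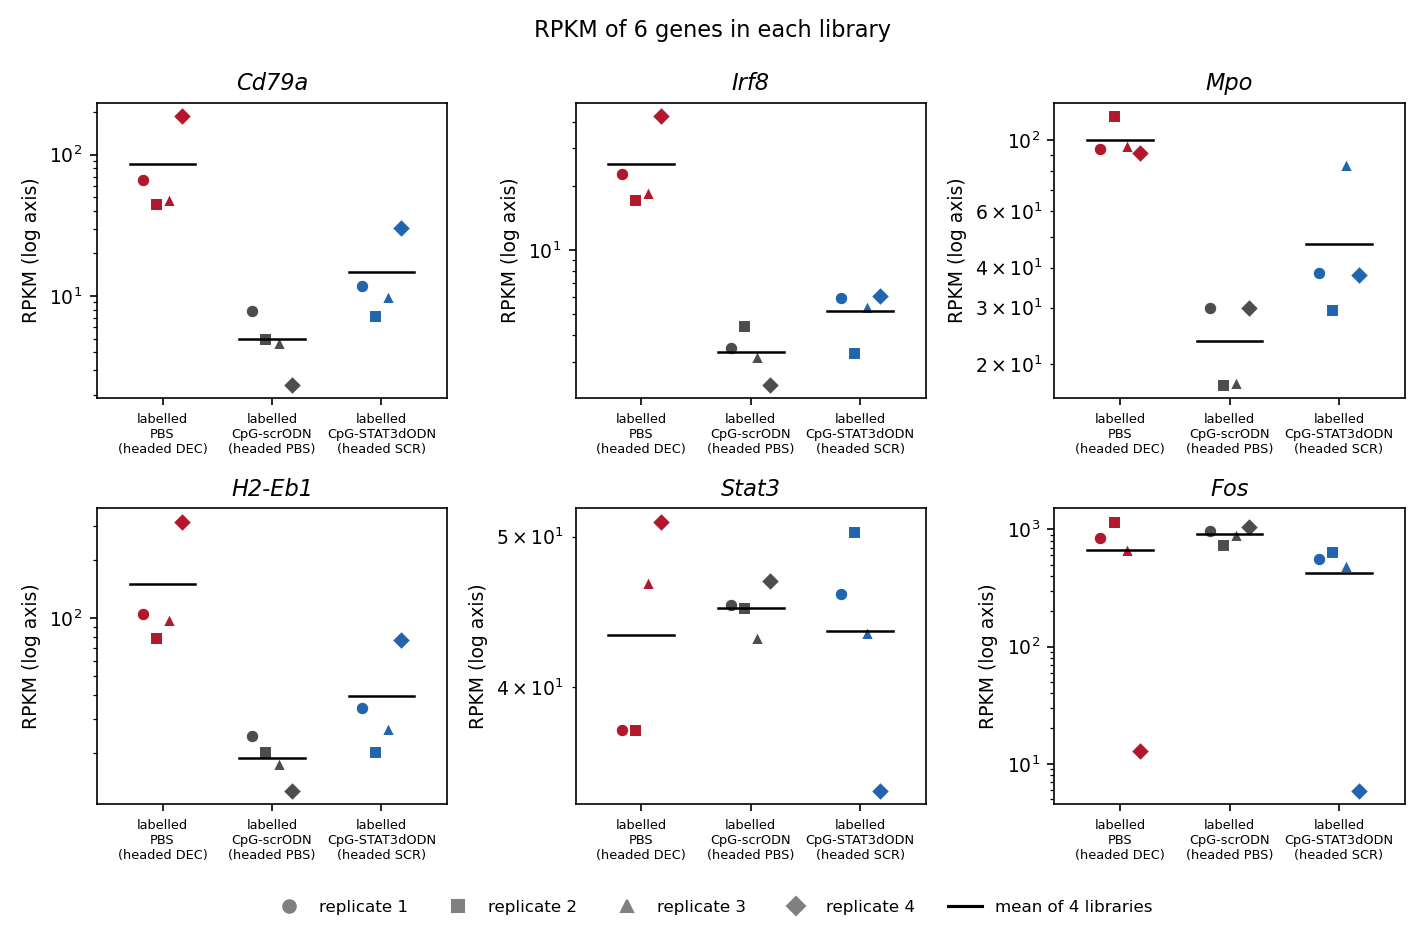
RPKM on a log axis of Cd79a, Irf8, Mpo, H2-Eb1, Stat3 and Fos in each of the 12 libraries by labelled group, with the header's group in brackets; symbols mark replicate numbers and lines the mean of 4 libraries. Cd79a, Irf8, Mpo and H2-Eb1 are higher in the 4 libraries labelled PBS than in the 4 labelled CpG-scrODN, Stat3 overlaps among all groups, and Fos falls to 12.9 and 5.91 RPKM in 2 libraries numbered 4.

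The second comparison set the libraries labelled CpG-STAT3dODN (headed SCR) against those labelled PBS (headed DEC). By the labels it asks what the decoy oligonucleotide changed, and by the headers it sets the scrambled against the decoy oligonucleotide. Irf8 was at 25.3 ± 11.7 RPKM (SD, n = 4) in the libraries labelled PBS and 5.18 ± 1.3 in those labelled CpG-STAT3dODN, a difference of -2.02 with a 95% interval of -2.61 to -1.44 (limma adjusted p = 0.00191). Ms4a1 was at 35.7 ± 12 and 3.34 ± 0.832 RPKM, with an interval of -3.59 to -2.49 (limma adjusted p = 0.000152). Mpo did not pass here. Its difference was -1.17 ± 0.29 (SE, limma adjusted p = 0.0806). In replicate 3 labelled CpG-STAT3dODN Mpo was at 84 RPKM, and in replicates 1, 2 and 4 at 38.4, 29.6 and 37.9 RPKM. Between the libraries labelled CpG-STAT3dODN and CpG-scrODN it differed by 0.91 (95% interval 0.27 to 1.54, limma adjusted p = 0.96), so the comparisons were not shown to differ for Mpo. Stat3 was at 43.5 ± 6.78 and 43.2 ± 6.82 RPKM, a difference of 0.01 with an interval of -0.27 to 0.29.

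Limma called 202 genes, 3 higher in the libraries labelled CpG-STAT3dODN and 199 higher in those labelled PBS, and 1023 at an unadjusted p under 0.05. The groups did not overlap in 5.04% of genes, where chance gives 2.86%. The 3 were Asap2 by 0.50, Schip1 by 0.49 and Abcg1 by 0.73 (limma adjusted p = 0.034), which falls outside the naming rule here and was chosen after its values were seen. Camera called 20 of 33 lists, 3 higher and 17 lower in the libraries labelled CpG-STAT3dODN. Of these calls 4 held with an estimated correlation and 7 with fry. The B-cell list had 14 of 16 genes passing over all genes and 16 adjusted over the list alone, higher in the libraries labelled PBS with a median of 2.22, Cd22 and Blnk by 2.78 and 2.62. Camera called it, with adjusted p = 0.0212 with an estimated correlation as well. The T-cell list (3 of 6 passed, 4 adjusted over the list alone), the conventional dendritic list (1 of 7, Wdfy4, and 3) and the plasmacytoid dendritic list (2 of 9, Ly6d and Spib, and 5) also kept their calls, with adjusted p = 0.0406, 0.0212 and 0.0212 with an estimated correlation. No library separates cell types, so these lists do not show signals apart from the B-cell list. With an RPKM floor of 5 the plasmacytoid dendritic median turned from -0.62 to 0.077, and without the filter on low values the conventional dendritic median went from -1.06 to -0.027 and its call was lost (adjusted p = 0.891).

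The MHC class II list, which moved with the B-cell list, had 8 of 16 passing and 14 adjusted over the list alone, among them H2-DMb2 by 2.12 and Ciita by 1.73, with adjusted p = 0.0636 with an estimated correlation. In the monocyte and macrophage list 5 of 28 passed (13 adjusted over the list alone), Ms4a4c and Ms4a6c by 2.04 and 1.5, with adjusted p = 0.0807 with an estimated correlation. The plasma cell list had 3 of 7 passing (4 adjusted over the list alone), with adjusted p = 0.0829 with an estimated correlation. The primary granule list was called with a median of 0.57 higher in the libraries labelled PBS, while 0 of its 20 genes passed limma over all genes and 12 passed adjusted over the list alone. Its adjusted p was 0.174 with an estimated correlation.

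The type I interferon, interferon gamma, TLR9 and NF-kB response, TLR9 signalling and MHC class I lists were called as lower in the libraries labelled CpG-STAT3dODN, with medians of -0.32, -0.64, -0.46, -0.11 and -0.13. All 5 calls were lost with an estimated correlation, with adjusted p = 0.186, 0.256, 0.181, 0.26 and 0.314. Over all genes 3 of 34, 3 of 22, 4 of 27, 2 of 24 and 2 of 22 passed. Adjusted over the list alone these counts were 6, 8, 8, 3 and 4, of which 1 of the interferon gamma and 1 of the NF-kB genes were higher there. Nfkbiz, an inducible NF-kB cofactor, and Il12a, a subunit of interleukin 12, were higher in the libraries labelled PBS by 0.98 and 0.77. The cell cycle, immediate-early and red pulp macrophage lists were also called as lower, with medians of -0.26, -0.55 and -0.45. Of their genes 0, 1 and 1 passed over all genes, Nr4a1 and Slc11a1, and 0, 1 and 2 adjusted over the list alone, with adjusted p = 0.397 each with an estimated correlation. The stem and progenitor, ribosomal protein and megakaryocyte lists were called as higher, with medians of 0.11, 0.11 and 0.40. In these 0 genes passed limma over all genes, 2, 0 and 0 passed adjusted over the list alone, and adjusted p was 0.162, 0.313 and 0.174 with an estimated correlation. The genes named with the study, of which Irf8, Ciita and Tlr9 passed (6 adjusted over the list alone, 1 of them in the other direction), had adjusted p = 0.299 with an estimated correlation. Among markers of other cells the erythroid, mature neutrophil and mast cell lists, with medians of -0.24, -0.31 and 0.25, were not called. Nor were STAT3 targets (-0.11), granulocyte maturation (-0.23), DNA and histone modifiers (-0.07), MYC and ribosome biogenesis (-0.05), p53 targets (0.06, mean -0.10), checkpoint ligands (0.09), oxidative phosphorylation (0.01), glycolysis (-0.02), the unfolded protein response (-0.07) and cholesterol synthesis (-0.10). For the erythroid and glycolysis lists camera's direction was opposite to the sign of the median.

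Limma called 5 genes with the B-cell list mean as a covariate, 78 with the fit on these groups only, 76 with an RPKM floor of 5 and 1248 with library quality weights, of which 651 were higher and 597 lower in the libraries labelled CpG-STAT3dODN. It called 121 without replicate 2 labelled CpG-STAT3dODN, 131 without replicate 1 labelled PBS, 337 without both libraries of low Fos, 392 without all 3 libraries numbered 4 and 338 with a term for replicate 4. The 3 genes higher in the libraries labelled CpG-STAT3dODN became 1, 1, 1 and 12 without its replicates 1, 2, 3 and 4, 0, 30 and 7 without replicates 1, 3 and 4 labelled PBS, 42 and 81 without both libraries of low Fos or all 3 numbered 4, 35 with the replicate 4 term, 12 with the replicate block, 11 with quantile normalization, 7 without the filter, 1 with the floor and 0 with 2 groups only. On leaving out 1 library, camera lost the calls of the immediate-early list (without replicate 4 labelled CpG-STAT3dODN or replicate 2 labelled PBS, with medians of -0.177 and -0.184), the red pulp macrophage list (without replicate 2 labelled PBS), the TLR9 signalling, MHC class I and stem and progenitor lists (each without replicate 4 labelled PBS, with medians of -0.043, -0.036 and 0.094) and the genes named with the study (without replicate 3 or 4 of either group). Limma's calls of Asap2, Schip1, Tlr9, Ccl5, Cd40, Cd79a, Derl3, H2-DMb2, H2-Eb2, H2-Ob, H2-Q4, Ifi27l2a, Lck, Ms4a4c, Ms4a6b, Nlrc5, Nr4a1, Pou2af1, Slc11a1 and Trim30a were each lost without at least 1 of the libraries, with differences within 1.5 times of the value from all libraries, and those of Ciita, Gbp9, Il12a, Ms4a6c and Cd3g were lost with the fit on these groups only. Camera's calls also ended without the filter for the stem and progenitor, megakaryocyte and red pulp macrophage lists (medians of 0.014, 0.149 and -0.227), with the floor for the red pulp macrophage list (-0.508) and with quality weights for the TLR9 signalling list (-0.066). The call of the genes named with the study ended without the filter, with the floor (0.002), with quality weights (-0.024), with the replicate block, with the replicate 4 term, and without both libraries of low Fos or all 3 numbered 4. With a pseudocount of 0.1 the differences of Gbp9, Cd40, Il12a, Tlr9, H2-Eb2, Cd3g, Lck and Derl3, whose call was then lost, were over 1.5 times as large, and those of Ms4a6b and Ms4a6c were -0.987 and -0.914 with quality weights.

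The third comparison set the libraries labelled CpG-STAT3dODN (headed SCR) against those labelled CpG-scrODN (headed PBS). By the labels it compares oligonucleotides that share the CpG part and differ in the decoy or scrambled sequence, and by the headers it sets the scrambled oligonucleotide against PBS. No gene passed: limma called 0 of 10886, 295 had an unadjusted p under 0.05, and the lowest adjusted p was 0.96. The groups did not overlap in 4.25% of genes, where chance gives 2.86%. The intervals leave room for differences of moderate size. That of Irf8 was 0.50, with a 95% interval of -0.08 to 1.09, from 5.18 ± 1.3 and 3.34 ± 0.861 RPKM (SD, n = 4). The interval was -0.34 to 0.22 for Stat3, 0.08 to 0.72 for Myc, -0.24 to 1.04 for Ciita, -0.39 to 0.94 for Tlr9, -0.01 to 1.06 for Itgam, the integrin CD11b, and -0.37 to 0.19 for Dnmt1, a DNA methyltransferase.

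Camera called 8 lists, and 0 of these passed with an estimated correlation or with fry. Immediate-early genes were lower by camera in the libraries labelled CpG-STAT3dODN, one of which was the replicate 4 library with low Fos, with a median of -1.09, 0 of 21 passing over all genes and 7 adjusted over the list alone. Adjusted p was 0.293 with an estimated correlation. The list means differed by -1.003 over all libraries. Against the mean of the libraries labelled CpG-scrODN, replicate 4 labelled CpG-STAT3dODN was at -2.42 and the mean of its replicates 1 to 3 at -0.53. The red pulp macrophage and glycolysis lists were lower by camera, with medians of -0.29 and -0.08, and adjusted p = 0.526 each with an estimated correlation. Both calls were lost without replicate 4 labelled CpG-scrODN, with medians of -0.083 and -0.073, and with quality weights, with medians of 0.197 and -0.001. The red pulp call was also lost without all 3 libraries numbered 4, with a median of 0.078. B-cell genes were higher by camera in the libraries labelled CpG-STAT3dODN, with a median of 0.52, 0 of 16 passing over all genes and 8 adjusted over the list alone, and adjusted p = 0.293 with an estimated correlation. Granulocyte maturation, primary granule, MHC class II and plasma cell genes were higher by camera, with medians of 0.77, 0.38, 0.46 and 0.43. In these 4 lists 0 genes passed limma over all genes or adjusted over the list alone, and adjusted p was 0.526, 0.451, 0.526 and 0.354 with an estimated correlation. The primary granule mean was 4.605 in replicate 3 labelled CpG-STAT3dODN and 3.793 to 3.983 in its replicates 1, 2 and 4. The granulocyte maturation mean was 5.431 in that replicate 3 and 4.163 to 4.737 in replicates 1, 2 and 4. Among the other cell types the T-cell, erythroid, megakaryocyte, conventional dendritic, plasmacytoid dendritic, mature neutrophil and mast cell lists were not called, with medians of 0.12, 0.19, -0.06, 0.34, 0.08, 0.38 and 0.07. Nor were the genes named with the study (0.10), type I interferon (0.10), interferon gamma (0.20), TLR9 and NF-kB response (0.20), STAT3 target (0.01), MHC class I (0.16), monocyte and macrophage (0.11), stem and progenitor (0.02, mean -0.01), cell cycle (-0.02, mean 0.01), TLR9 signalling (0.045), DNA and histone modifier (-0.006), MYC and ribosome biogenesis (-0.027), p53 target (0.006), checkpoint ligand (0.148), oxidative phosphorylation (0.016), unfolded protein response (0.155), cholesterol synthesis (0.185) or ribosomal protein (0.049) lists. For the T-cell, mast cell, stem and progenitor, p53 and oxidative phosphorylation lists camera's direction was opposite to the sign of the median.

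Library quality weights, whose estimate did not fully converge, called 607 genes in this comparison (532 higher and 75 lower in the libraries labelled CpG-STAT3dODN). The fit on these 2 groups only called 1, Hist1h2an, named after its value was seen. Grouping by the headers, which turns this comparison into another one, gave 202, and the other settings tried gave 0. Camera called 15 lists without replicate 4 labelled CpG-STAT3dODN, 15 without replicate 1 labelled CpG-scrODN, and 20 without all 3 libraries numbered 4.

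**Figure D3:**
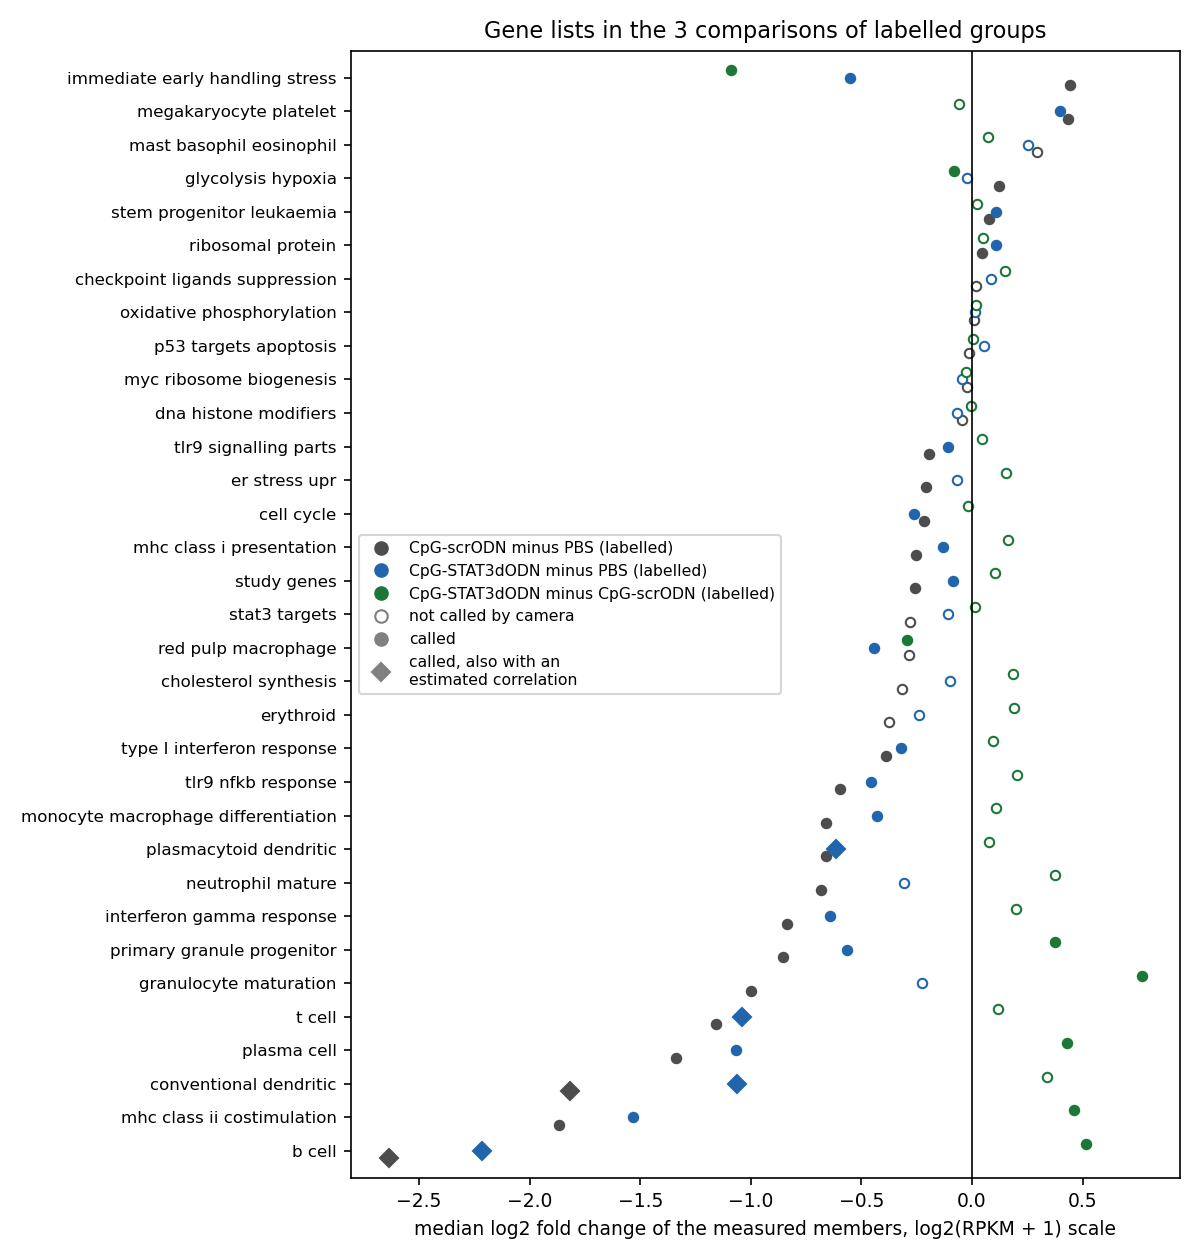
Median log2 fold change of the measured members of 33 gene lists in the 3 comparisons of labelled groups; filled symbols were called by camera and diamonds were also called with an estimated correlation. The B-cell list lies at -2.64 and -2.22 against the libraries labelled PBS and at 0.52 between the other groups.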

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

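The test of the label order in the type I interferon list and the counts of splits were fixed before the values were seen, and the other tests given here were chosen after.

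In 11 of 144 groups of 4 libraries 1 library lay far from the other 3 on the log2 scale by Dixon's criterion, the gap to the nearest other over the range, where chance gives about 1 in 20, and in each of the 11 that library was numbered 4. In replicate 4 labelled CpG-STAT3dODN, the TLR9 and NF-kB response list mean was 3.64 (nearest other 2.97), the immediate-early list 4.07 (5.83), the ribosomal protein list 9.73 (9.57), Spi1 6.59, Dnmt3a 3.12 and the costimulator Cd86 3.18 (0.99). In replicate 4 labelled PBS, the MHC class II list was 5.88 (4.68), the MHC class I list 6.24 (5.68), the T-cell list 4.09 (3.08) and Cd86 4.69 (1.27). The ribosomal protein list was 9.41 in replicate 4 labelled CpG-scrODN.

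The type I interferon list was lowest in the libraries labelled CpG-scrODN, not in those labelled PBS. Its median, labelled CpG-scrODN (headed PBS) minus labelled PBS (headed DEC), was -0.39, and camera called it. CpG oligonucleotides stimulate TLR9, which drives interferon genes, so the libraries labelled PBS should be lowest if the labels are right. A candidate explanation is that labels were attached to the wrong files and the headers carry the true groups. By the headers, the third comparison sets the scrambled CpG oligonucleotide against PBS and should then show a rise. There the type I interferon list was not called (median 0.096, camera adjusted p = 0.407). Nor was the TLR9 and NF-kB response list (median 0.202, camera adjusted p = 0.905). The call in the first comparison was lost with an estimated correlation (adjusted p = 0.278), and B-cell genes were higher in the same libraries. Which of the names is right therefore remains open.

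B-cell genes were higher in the libraries labelled PBS in 16 of 16 members, of which 1 reached a mean of 5 RPKM in the libraries labelled CpG-scrODN. A smaller share of leukaemia cells would raise other spleen cell types alike. The B-cell list rose beyond the erythroid, red pulp macrophage and megakaryocyte lists by 2.33, 2.72 and 3.21 (exact permutation p = 0.0286 each), but these have median levels of 29.4, 5.64 and 15.1 RPKM in the libraries labelled CpG-scrODN, which would hide a small share. The T-cell, conventional dendritic and plasma cell lists were at 0.774, 0.868 and 2.54 RPKM there. Their list means rose by 1.27, 1.58 and 1.63 (exact permutation p = 0.0286 each). Of their genes in the data, 6 of 22, 7 of 20 and 7 of 10 passed the filter on low values. A gene can pass that filter through 1 group alone, which favours genes high in the libraries labelled PBS. Without the filter the conventional dendritic median, labelled CpG-scrODN minus labelled PBS, went from -1.82 to -0.101. The conventional dendritic list therefore cannot show that other cell types rose. Camera's calls of the T-cell and plasma cell lists were not lost without the filter. Neither held with an estimated correlation (camera adjusted p = 0.121 and 0.0924). These lists do not settle whether other cell types rose, and a smaller share of leukaemia cells stays open. B-lineage cells carried through the selection could account for the 16 genes and stay open with a change in the leukaemia cells themselves, since no library separates cell types and c-Kit selection or a GFP sort should remove mature B cells. Kit, the gene of the selection marker, was at 21 ± 12.4 RPKM in the libraries labelled PBS and 32.2 ± 5.67 in those labelled CpG-scrODN. The groups overlapped, and the difference of 0.75 (95% interval 0.001 to 1.493) did not pass (limma adjusted p = 0.319). Kit therefore does not decide how pure the libraries were. With the B-cell list mean as a covariate the Irf8 difference went from -2.53 (SE 0.27) to 0.16 (SE 0.45), but group explained 0.92 of that mean, so for Irf8 carried cells and a change in the leukaemia cells cannot be told apart. In the primary granule list, which shares 0 genes with the B-cell list and holds products of myeloid cells, 12 of 20 were also higher there, which argues against carried B cells as the source of that part, while other carried myeloid cells and the treatment stay open.

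Immediate-early genes were low in replicate 4 labelled PBS and replicate 4 labelled CpG-STAT3dODN, with 11 of 21 members under each of the other 10 libraries. The shallower of these had 0.91 of the median depth of the others, which argues against lower depth. Against the libraries labelled CpG-scrODN, the list mean of replicate 4 labelled PBS was at -2.14 and that of replicates 1 to 3 at 0.18, and for the libraries labelled CpG-STAT3dODN these values were -2.42 and -0.53. This argues against the treatments as the whole source of the low values. Replicates 1 to 3 labelled CpG-STAT3dODN, at 5.83 to 6.03, were still each below the lowest library labelled CpG-scrODN, at 6.27, so a smaller lowering in that group stays open. Different handling after harvest could account for the 11 genes and stays open, since the labels give no date or batch.

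For CpG-scrODN against PBS, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one with 452 genes, gave as many, and the highest of the others gave 0. A share of 1 in 35 is under 0.05, but it is the smallest this count can give and was not adjusted over the 3 comparisons. Chance assignment of these 8 libraries to groups is therefore unlikely by this count, though not excluded. The count does not cover chance differences between mice or batches, since nothing says that 1 library stands for 1 mouse. For CpG-STAT3dODN against PBS 3 of 35 gave at least the real 202. The highest other gave 877 and set PBS replicates 1, 2 and 4 with CpG-STAT3dODN replicate 4 against the rest, which points to a structure of the samples, since it sets the 2 libraries of low immediate-early genes on one side. Chance is not excluded by this count, which takes no account of that structure. With a term for replicate 4 limma called 338 genes, and 337 without these 2 libraries. For CpG-STAT3dODN against CpG-scrODN limma called 0 genes (295 at an unadjusted p under 0.05), so 35 of 35 splits had to give at least as many (0 in the highest other), and the count decides nothing.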

How the results depend on the processing

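Groups are named here by their labels. The alternatives that left out or modelled replicate 4 libraries and the one with a B-cell covariate were chosen after the data were seen. Leaving out the B-cell covariate and the file names' grouping, 0 of the named genes that were called turned direction under any alternative, and 2 called lists turned camera's direction, both under library quality weights, immediate-early at -0.043 for CpG-scrODN against PBS and red pulp macrophage at 0.20 for CpG-STAT3dODN against CpG-scrODN (a weight estimate that did not fully converge). The cause was not tested. The weights were the same in all 3 comparisons, so this limit holds for every count with quality weights. The sign of the median alone turned for immediate-early without PBS replicate 4 or both libraries of low immediate-early genes (-0.073) and without all 3 libraries numbered 4 (-0.060), for glycolysis with quality weights (-0.041) and without all 3 (-0.027), for red pulp macrophage in the third comparison without all 3 (0.078), and with an RPKM floor of 5 for plasmacytoid dendritic (0.112 and 0.077 in the comparisons with PBS) and, in the second, study genes (0.002). Genes called for CpG-scrODN against PBS, 452 in the report, were 163 with an RPKM floor of 5, where fewer genes were tested, 1812 with quality weights (730 and 1082 higher and lower), 686 without the 2 libraries of low immediate-early genes and 871 with a replicate 4 term. Leaving out 1 library gave 279 to 560, the lowest without CpG-scrODN replicate 3. For CpG-STAT3dODN against PBS, 202 in the report, they were 76 with the floor, 1248 with quality weights (651 and 597 higher and lower), 78 with 2 groups only, 337 without the 2 libraries, 392 without all 3 libraries numbered 4 and 338 with the replicate 4 term. Leaving out 1 library gave 121 to 218, with 121 without CpG-STAT3dODN replicate 2 and 131 without PBS replicate 1. For CpG-STAT3dODN against CpG-scrODN, limma's 0 (295 at an unadjusted p under 0.05) became 607 with quality weights (532 and 75 higher and lower) and 1 with 2 groups only, and stayed 0 to 0 on leaving out 1 library. Camera called 23, 20 and 8 lists, of which 2, 4 and 0 held with an estimated correlation, and 15, 7 and 0 with fry. In the first comparison fry also called STAT3 targets and p53 targets, which camera did not (fry adjusted p = 0.00285 and 0.0203). For the third comparison camera's calls were 15 with quantile normalization, 17 with quality weights, and 16 and 20 without the 2 or all 3 libraries numbered 4. Leaving out 1 library gave 19 to 23, 18 to 22 and 9 to 15 lists, with 15 without CpG-STAT3dODN replicate 4 or CpG-scrODN replicate 1. With a replicate block the counts of genes were 523, 213 and 0. The numbers were not taken as pairs, since 5 of 12 correlations of same-numbered libraries were above 0.1. In 3 of the 12 checks a library correlated best with its own number. Those 3 were the replicate 4 pairs, at 0.19, 0.82 and 0.15 in the order of the comparisons. Replicate 1 of the second comparison reached 0.33 and replicate 2 of the first 0.21. By these correlations over all genes, only replicate 4 labelled CpG-STAT3dODN and replicate 4 labelled PBS, at 0.82, stood out as deviating together. In heat-shock genes all 3 libraries numbered 4 were low. Labelled PBS, CpG-scrODN and CpG-STAT3dODN, they had Hspa1a at 1.87, 2.38 and 2.6 RPKM, against 31.6 to 520 elsewhere. Hspa1b was at 10.4, 8.28 and 13.2 RPKM, against 236 to 2430 elsewhere. A feature shared by all 3 therefore stays open. With the B-cell covariate 0, 5 and 0 genes and 11, 10 and 9 lists were called, and 30 of 68, 26 of 51 and 7 of 15 named genes kept their direction. Standard errors widened, that of Irf8 from 0.27 to 0.45 and of Mpo from 0.29 to 1.04, since the group explained 0.92 of the covariate's variance. Gene differences called without the covariate turned sign with it at these log2 values, called lists turned camera's direction, which is taken against all other genes, and the same confounding of covariate and group stands behind each, so the cause was not tested further. For CpG-scrODN minus PBS the values were Egr4 -1.28, Abcg1 -0.185, Bex4 -0.56, Ephx4 -0.070, Cd79b 3.22, Cd79a 1.80, Fcrla 0.78, Cd83 3.96, Ifi27l2a 1.63, Trim30a 0.54, Cmpk2 0.84, Ciita 0.51, Nlrc5 1.07 and Gbp9 0.445. Further values were Gbp4 1.44, Cd40 0.54, Tlr9 1.15, H2-DMb2 1.52, H2-Ob 1.62, H2-Eb1 2.31, Cd74 1.965, H2-Q7 2.205, H2-Q6 1.52, H2-Q4 0.82, Irf8 0.16, Ms4a4c 1.79, Plac8 1.76 and Pou2af1 1.39. Further values were Cd2 0.38, Lck 0.55, Spib 0.64 and Tcf4 0.68. List medians there were study genes 0.10, type I interferon 0.58, interferon gamma 1.00, NF-kB response 0.62, TLR9 signalling 0.18, MHC class II 1.14, MHC class I 0.505, stem and progenitor -0.615, glycolysis -0.59, unfolded protein response 0.29, immediate-early -3.328, plasma cell -0.13, T-cell 0.067 and megakaryocyte -0.89. For CpG-STAT3dODN minus PBS the genes were at Fcrla 0.34, Cd72 0.085, Cd79a 1.72, Ifi27l2a 0.865, Trim30a 0.33, Ciita 0.25, Nlrc5 0.60, Gbp9 0.11, Cd40 0.395, Tlr9 0.72, H2-DMb2 1.31, H2-Ob 1.44, H2-Eb2 0.84 and H2-Q4 0.53. Further values were Ms4a4c 1.102, Mzb1 0.032, Pou2af1 1.39, Lck 0.20 and Spib 0.53. List medians in that comparison were study genes -0.010, type I interferon 0.555, interferon gamma 0.64, NF-kB response 0.49, TLR9 signalling 0.11, MHC class II 0.74, MHC class I 0.43, stem and progenitor -0.45, plasma cell 0.345 and megakaryocyte -0.61. For CpG-STAT3dODN minus CpG-scrODN the lists were at MHC class II -0.25, glycolysis 0.006, B-cell 0.009 and red pulp macrophage 0.20. The medians themselves kept their sign for plasma cell in the first, study genes in the second and B-cell in the third comparison. Grouping by the file names gave 0, 452 and 202 genes and 8, 23 and 20 lists, because each comparison then becomes another one of the labelled groups. By that construction its values are those of the third, the first and the second comparison, the last 2 with the sign turned. Differences that turned sign for CpG-scrODN minus PBS were Egr4 -1.70, Perp -0.069, Abcg1 -0.096, Bex4 -0.14, Ephx4 -0.063, Cdkn1a -0.14, Rarres1 -0.077, Ly6d 0.85, Cd79b 1.38, Ms4a1 0.80, Cd79a 1.295, Fcrla 0.68, Cd72 0.98 and Cd83 1.00. Further values were Ifi27l2a 0.20, Ifi203 0.185, Trim30a 0.30, Cmpk2 0.43, Ciita 0.40, Nlrc5 0.21, Gbp9 0.185, Gbp4 0.20, Ccl5 0.44, Cd40 0.39, Ccl3 0.18, Unc93b1 0.46, Tlr9 0.275 and H2-DMb2 0.93. Further values were H2-Ob 0.97, H2-Eb1 0.88, Cd74 0.98, H2-Q7 0.69, H2-Q6 0.73, H2-Q4 0.175, Irf8 0.50, Ms4a4c 0.36, Ms4a6b 0.18, Ly6c2 0.74, Cebpe 0.965, Plac8 0.74, Ctsg 0.89 and Mpo 0.91. Further values were Prtn3 0.91, Dnajb9 0.155, Mzb1 0.905, Jchain 1.25, Pou2af1 1.02, Derl3 0.275, Cd2 0.32, Cd3g 0.19, Lck 0.046, Wdfy4 0.34, Spib 0.85, Lag3 0.076, Tcf4 0.175 and Itgam 0.52. Lists that turned camera's direction were study genes 0.10, type I interferon 0.096, interferon gamma 0.20, NF-kB response 0.20, TLR9 signalling 0.045, MHC class II 0.46, MHC class I 0.16, monocyte 0.11, granulocyte maturation 0.77, primary granule 0.375, stem and progenitor 0.022, glycolysis -0.080, unfolded protein response 0.155 and immediate-early -1.09. Further values were B-cell 0.52, plasma cell 0.43, megakaryocyte -0.058, conventional dendritic 0.34, plasmacytoid dendritic 0.076 and mature neutrophil 0.375. Of these the stem and progenitor median kept its sign. For CpG-STAT3dODN minus PBS the differences that turned were Asap2 -0.43, Schip1 -0.31, Ly6d 4.37, Ms4a1 3.84, Fcrla 3.69, Cd2 3.14, Cd22 3.14, Blnk 3.315, Cd72 3.56, Cd79a 3.70, Ifi27l2a 2.20, Ifi203 1.66, Trim30a 1.48 and Ciita 2.13. Further values were Nlrc5 1.65, Gbp9 1.62, Ccl5 1.685, Cd40 1.605, Nfkbiz 0.69, Il12a 0.98, Unc93b1 2.255, Tlr9 1.67, H2-DMb2 3.045, H2-Ob 2.92, H2-Eb2 1.996, H2-Q4 1.05, Ms4a4c 2.40 and Irf8 2.53. Further values were Ms4a6b 1.73, Ms4a6c 1.51, Nr4a1 0.079, Mzb1 3.09, Pou2af1 2.665, Derl3 1.34, Cd3g 1.299, Lck 1.02, Wdfy4 1.82, Spib 3.17, Slc11a1 0.86 and Itgam 0.97. Its lists that turned camera's direction were study genes 0.26, type I interferon 0.39, interferon gamma 0.84, NF-kB response 0.60, TLR9 signalling 0.20, MHC class II 1.87, MHC class I 0.25, monocyte 0.66, primary granule 0.85, stem and progenitor -0.078, cell cycle 0.22, ribosomal protein -0.047, B-cell 2.64 and plasma cell 1.34. Further values were T-cell 1.16, megakaryocyte -0.435, conventional dendritic 1.82, plasmacytoid dendritic 0.66 and red pulp macrophage 0.29. In the third comparison the lists that turned camera's direction were immediate-early 0.55 and red pulp macrophage 0.445. Depth differed by a ratio of 1.15 between libraries and limits genes near an RPKM of 1, about 31.6 reads per kilobase.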

Other observations

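The gene family, the single genes and the tests given here were chosen after the values were seen.

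Histone genes of the replication-dependent clusters, which are transcribed in S phase, were lower in the libraries labelled CpG-STAT3dODN (headed SCR) than in those labelled CpG-scrODN (headed PBS). The mean of 46 measured members was 1.60 to 1.89 on the log2 scale in the first and 2.18 to 2.57 in the second, a difference of 0.52 (exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). It was 0.54 with size factor scaling, 0.56 with quantile normalization and 0.72 with a pseudocount of 0.1. The libraries labelled PBS spanned 1.64 to 2.35. The cell cycle list was not called between the first 2 groups, with a median of -0.017, 0 of 41 genes passing and a difference in list means of 0.012 (exact permutation p = 1). Hist1h2an differed by -1.60 when only these groups were fitted (limma adjusted p = 0.0184), and with all libraries in the model its adjusted p was 0.96. Members of this family are near copies of each other, and their values depend on how shared reads were assigned.

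Among the 12 genes higher in the libraries labelled CpG-scrODN than in those labelled PBS, those not named above were Afap1l1 by 1.52, C030034L19Rik by 1.298, Rcn1, a calcium-binding protein of the endoplasmic reticulum, by 0.38, and Sh3d19 by 0.37.

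Hspa1a, an inducible heat-shock chaperone with a near-identical copy, was at 1.87, 2.38 and 2.6 RPKM in the replicate 4 libraries labelled PBS, CpG-scrODN and CpG-STAT3dODN, and at 31.6 to 520 in the other libraries. Hbb-b1, an adult haemoglobin chain of red cells, ran from 74.4 to 4510 RPKM over the 12 libraries. Xist, the RNA of the inactive X chromosome, was at 19.1 and 17.6 RPKM in replicate 4 labelled PBS and replicate 4 labelled CpG-STAT3dODN, and at 42.6 to 77.5 in the other 10.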
